A study of Mus musculus with 35 samples.

How the data were processed

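RNA bound to tagged ribosomes was measured in 35 libraries from the myenteric plexus of mouse duodenum, ileum and colon. Per the labels' protocols, the plexus was dissected into a buffer with cycloheximide, which holds ribosomes on RNA, and homogenized. The tagged ribosomes were pulled down with an antibody against the HA epitope, and RNA was isolated from the beads. The design text names deep sequencing on an Illumina NextSeq. Each library has a deposited kallisto table of 105129 Ensembl transcripts. The transcripts were quantified with kallisto against build GRCm38.p5, per the submitters' processing notes, and the kallisto version is not given in the sources used here. Estimated counts, which need not be whole because kallisto divides reads that match several transcripts, were deposited by the authors for every transcript, per the file headers. The deposited tables also hold TPM (estimated counts scaled by effective length and by library total), per the file headers, and dividing the deposited estimated counts by the deposited effective lengths returned the TPM column to within a relative difference of 9.9e-06. Effective lengths were the same in all files, so an offset for transcript length per library changes nothing and was not fitted.

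The files do not pair transcripts with gene names. The gene table used here, for assembly GRCm38.p6, held 0 entries with an Ensembl identifier, so no transcript was tied to a gene and no gene name is given. The planned sums of transcripts per gene, the tests of gene lists fixed beforehand, and the look at Snap25 and Cartpt in every comparison were therefore not run, and each test was made per transcript on estimated counts rounded to whole numbers. A transcript can fall to 0 while its gene does not, when kallisto assigns shared reads to another transcript of that gene. No bootstrap of this assignment was used here, so the p-values leave it out.

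Groups and replicate numbers were taken from the sample titles. Cre-positive and Cre-negative pull-downs were compared within each region over germ-free and specific pathogen free mice together, in a fit of all 35 libraries with 12 groups. The interaction of Cre with microbiota used the same fit. Germ-free and specific pathogen free mice were compared within each region in a fit of the 19 Cre-positive libraries and, apart from it, in a fit of the 16 Cre-negative libraries. Regions were compared between specific pathogen free Cre-positive groups, and the interaction of region with microbiota was tested in the Cre-positive fit. Each fit used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with TMM scaling, the default expression filter on the groups of the fit and robust estimation, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The filter left 64798 transcripts in the fit of all libraries, 56732 in the Cre-positive fit and 59962 in the Cre-negative fit, with 23, 13 and 10 residual degrees of freedom. The common biological coefficient of variation was 0.82, 0.861 and 0.73 in the same order. A transcript counted as enriched in the pull-down of a region when it passed the threshold with a log2 fold change above 1.

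The class of enriched transcripts whose share of counts is reported for a region was taken from the other 2 regions, so that the libraries measured did not define it. Shares per library were compared with exact two-sided permutation tests over the 9 comparisons of each measure, with Benjamini-Hochberg adjustment. Named transcripts have the largest fitted changes in either direction among those past the threshold whose log2 CPM (prior count 2) did not overlap between the groups compared, or, for interactions, the smallest p. At most 2 that rose and 2 that fell are printed per comparison, and for pull-down, Cre-negative and region comparisons only those selected in at least 2 comparisons. This differs from the rule fixed before the data were examined, and was applied to transcripts and shortened because they have no names. The fixed rule took Cre-negative results by the smallest p and region results separately within and outside the enriched sets. It did not require selection in at least 2 comparisons. CPM values are scaled by TMM. A fold against a group at 0 in all libraries is a lower bound computed against 3 counts in each library of that group. Where that group held 1 or 2 counts in total, the ratio has a 95% Poisson interval. Bounds and intervals cover counting error only.

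The tests were tried on simulated counts with known changes. They were drawn from the mean of each transcript over the libraries of the fit, the library sizes and the fitted dispersion trend. Each transcript had the same mean in every group apart from the set changes. The simulation held no sparse libraries, shifts in composition or reads reassigned between transcripts. For germ-free against specific pathogen free mice among 56732 Cre-positive transcripts simulated, 4-fold changes were recovered at 4.48% in duodenum, 20% in ileum and 4.69% in colon, and 16-fold changes at 42.4%, 69.7% and 42.4%. In the fit of 64798 transcripts, 4-fold pull-down changes were recovered at 20.3% in duodenum, 33.8% in ileum and 16.7% in colon. False calls numbered 0 to 4 per comparison in this simpler setting, which does not give their number in the real libraries.

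Total estimated counts per library ranged from 19013849 to 41857261 with a median of 26598306. No pair of libraries among 595 held identical values, and the highest Spearman correlation between any pair was 0.895. For each library the share of counts in transcripts of up to 1000 bases was computed. A second measure took transcripts whose median lay between 3 and 10 CPM in the libraries of the other groups with the same Cre status, and gave the share of them with at most 2 counts. Libraries above 8% on this measure, a limit set after the data were examined, are called sparse here.

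Alternatives fixed before the data were examined were RLE size factors, library size without a composition factor, no expression filter, limma-voom (limma 3.58.1) with sample quality weights, DESeq2 1.42.0, a fit of the compared groups alone, each library left out in turn, a replicate block, and pull-down enrichment within each microbiota status. Fits without the sparse libraries, with the short-transcript share as a covariate, with all Cre-positive libraries thinned to one depth, and region contrasts in germ-free mice were added after the data were examined. Other splits of the samples were drawn up to 100 per comparison. For splits in the fit of all libraries the dispersion trend of the real groups was kept.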

Results

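Ribosome-bound RNA was profiled in the myenteric plexus, the nerve layer between the muscle coats of the gut wall, of mouse duodenum, ileum and colon. In Snap25:RiboTag mice, Cre recombinase under the neuronal gene Snap25 switches on an epitope tag on a ribosomal protein, and pulling down the tag recovers RNA from ribosomes of those cells. The same pull-down from Cre-negative mice, in which the tag stays off, gave the background. Mice were germ-free (GF, kept without microbes) or specific pathogen free (SPF, carrying a microbiota without listed pathogens). The 35 libraries formed 12 groups. In duodenum each of the 4 groups had 3 libraries. In ileum the SPF Cre-positive group had 5 and the other groups 3 each. In colon the SPF Cre-positive group had 3 and the other groups 2 each. Total estimated counts per library were 19013849 to 41857261, with a median of 26598306. The labels number libraries without stating that each came from its own mouse, so p-values measure the spread between these libraries, which may be technical in part. The names of all SPF tables, and of no GF table, carry the word diet, which the labels do not explain, so a difference in diet between GF and SPF mice is not excluded.

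Cre-positive and Cre-negative libraries lay apart on the first principal component, which held 26.2% of the variance. The second held 20.3%, and 4 SPF libraries lay at its far end, with scores from 311 to 406.8. These were ileum SPF Cre-positive replicates 2 and 4, colon SPF Cre-positive replicate 3 and ileum SPF Cre-negative replicate 4. They also had the most missing transcripts of middle abundance, at 16.6%, 11.7%, 18.6% and 8.15% in that order. They are called sparse libraries from here on.

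**Figure D1:**
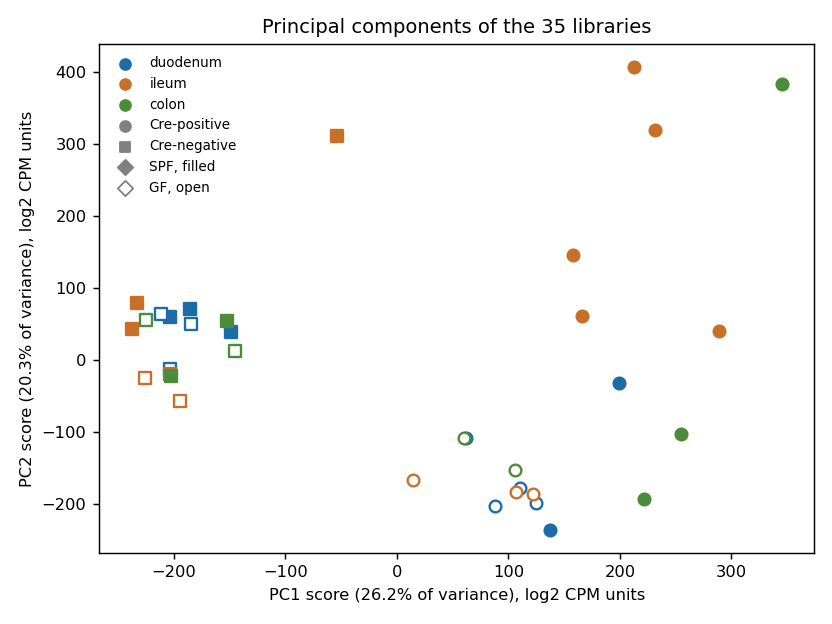
Scores of the 35 libraries on the first 2 principal components of log2 CPM, 1 point per library, with colours for regions, circles for Cre-positive, squares for Cre-negative, filled symbols for SPF and open symbols for GF. The 4 sparse libraries have second-component scores from 311 to 406.8.

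The first question was which transcripts the tagged ribosomes carry above background. In duodenum 9408 of 64798 transcripts were over 2-fold higher in the pull-down of Cre-positive mice than in that of Cre-negative mice, 8726 in ileum and 8683 in colon. Many were shared between regions, whose libraries are separate: 5600 transcripts were enriched in all 3, where independent lists would share 170. Another 3863 were over 2-fold lower in all 3, against 205 for independent lists. Across transcripts, which are not independent replicates, log2 fold changes in pairs of regions had Spearman correlations of 0.62 to 0.67. Opposite calls between pairs of regions numbered 23 to 49 transcripts.

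Transcripts enriched in the other 2 regions took up 45.55% to 57.69% of counts in every Cre-positive library. In duodenum this class of 6703 transcripts held 53.0% ± 4.48 of counts in SPF Cre-positive libraries (SD, n = 3) and 51.6% ± 0.886 in GF Cre-positive libraries (SD, n = 3), against 18.0% ± 1.9 and 18.1% ± 0.806 in the matching Cre-negative libraries (SD, n = 3 each). In ileum the class of 6195 transcripts held 50.7% ± 3.95 (SD, n = 5) and 49.1% ± 2.76 (SD, n = 3), against 14.4% ± 1.96 and 16.5% ± 1.56 in Cre-negative libraries (SD, n = 3 each). In colon the class of 6676 transcripts held 55.4% ± 1.82 (SD, n = 3) and 49.4% ± 3.23 (SD, n = 2), against 15.5% ± 0.0468 and 16.8% ± 4.56 (SD, n = 2 each). All 19 Cre-positive libraries lay between 45.55% and 57.69%, above all 16 Cre-negative libraries, at 13.26% to 20.1%. Exact two-sided permutation tests of Cre-positive against Cre-negative libraries gave the smallest p their sizes allow, 0.00216 in duodenum, 0.000333 in ileum and 0.00794 in colon, or 0.00972, 0.003 and 0.0238 after Benjamini-Hochberg adjustment over 9 comparisons. Between GF and SPF libraries of the same Cre status and region, the exact two-sided permutation p for this share was lowest in Cre-positive colon, at 0.1 (0.225 adjusted over the 9 comparisons), the smallest its sizes allow, and it was not under 0.2 in the other 5 comparisons. In Cre-positive colon the GF libraries, at 47.13% and 51.71%, lay below the SPF libraries, at 53.36% to 56.89%. Only Cre-positive ileum, with a smallest possible p of 0.0179 in this permutation test, had the sizes to fall under 0.05. These p-values therefore do not show equal shares.

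**Figure D2:**
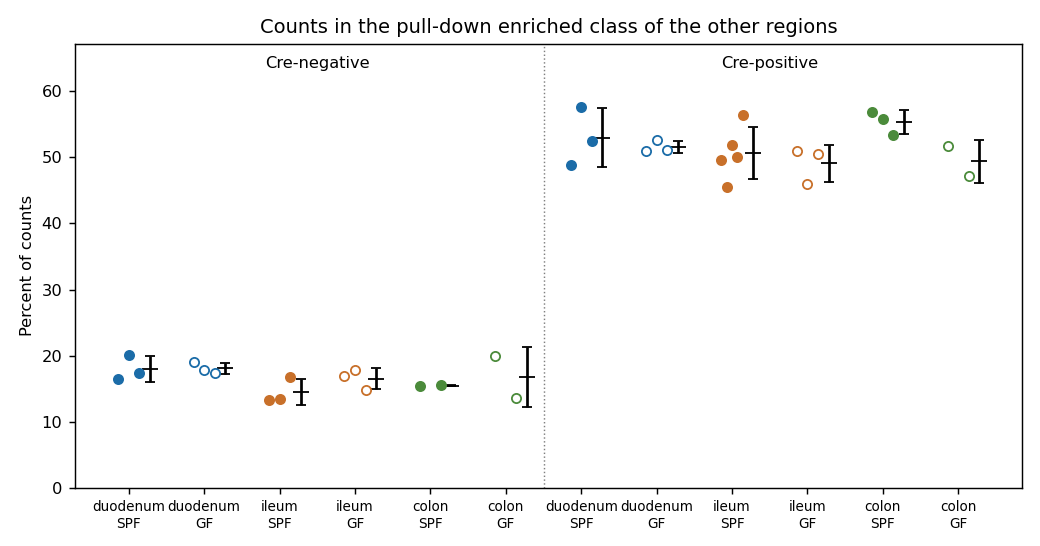
Percent of estimated counts per library in transcripts enriched by the pull-down in the other 2 regions (vertical axis), by group, 1 point per library, filled for SPF and open for GF. Black bars give the mean and SD. Cre-positive libraries lie between 45.55% and 57.69%.

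ENSMUST00000176268.1 was at 42.5 CPM ± 25.0 in Cre-positive ileum libraries (SD, n = 8) and at 50.6 CPM ± 29.5 in Cre-positive colon libraries (SD, n = 5), and had 0 counts in all Cre-negative libraries of both regions. It was at least 410-fold higher in ileum and at least 640-fold higher in colon, with adjusted p of 2.11e-11 and 9.86e-10 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. ENSMUST00000163668.2 was at least 386-fold higher in duodenum and at least 315-fold higher in ileum (edgeR adjusted p of 6.6e-09 and 7.84e-09). ENSMUST00000116371.7 went the other way. It was at 31.2 CPM ± 1.85 in Cre-negative colon libraries (SD, n = 4) and had 0 counts in the 5 Cre-positive colon libraries, at least 263-fold lower (edgeR adjusted p of 1.58e-07). In ileum it had 1 count over the 8 Cre-positive libraries against 43.5 CPM ± 25.0 in 6 Cre-negative libraries (SD), a ratio of 6570 with a counting interval of 1180 to 260000 (edgeR adjusted p of 5.34e-09). With library size as the only scaling, the enriched transcripts numbered 6032 in duodenum, 5601 in ileum and 5245 in colon. That scaling moved the median log2 fold change of all transcripts by -0.54, -0.49 and -0.62, and of the transcripts called in either direction 29.3%, 29.5% and 26.6% were then higher in the pull-down, against 50.4%, 51.6% and 48.5% with TMM, so enrichment is relative to the scaling. Within GF mice alone they numbered 6187, 4923 and 3754, and within SPF mice alone 6207 in duodenum.

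The second question was how the RNA on tagged ribosomes differed between GF and SPF mice. In ileum 4315 of 56732 transcripts differed, 2701 higher and 1614 lower in GF mice, with a median absolute log2 fold change of 1.91. ENSMUST00000060766.15 was at 121 CPM ± 28.0 in GF ileum (SD, n = 3) and had 0 counts in all 5 SPF libraries, at least 1010-fold higher (edgeR adjusted p of 0.00783). ENSMUST00000119978.1 was at 99.8 CPM ± 15.5 in GF ileum (SD, n = 3) and had 0 counts in the SPF libraries, at least 831-fold higher (edgeR adjusted p of 0.0226). Lower in GF mice was ENSMUST00000129314.1, at 53.5 CPM ± 13.7 in SPF ileum (SD, n = 5) and 0 counts in the 3 GF libraries, at least 346-fold lower (edgeR adjusted p of 0.000139). ENSMUST00000210815.1 was at 342 CPM ± 266 in SPF ileum (SD, n = 5) and had 1 count over the GF libraries, a ratio of 20900 with a counting interval of 3760 to 827000 (edgeR adjusted p of 0.0306). ENSMUST00000129314.1 also had 0 counts in all 3 GF Cre-negative ileum libraries, against 29.5 CPM ± 29.4 in SPF Cre-negative ileum (SD, n = 3). Libraries within other SPF groups differed widely too. ENSMUST00000060766.15 was at 0 to 107 CPM in SPF Cre-positive colon (n = 3) and ENSMUST00000119978.1 at 0 to 94.8. ENSMUST00000210815.1 and ENSMUST00000129314.1 were there at 1.03 to 1610 and 21 to 89.2. In SPF Cre-positive duodenum (n = 3) the first 2 were at 25.7 to 178 and 0 to 177 CPM. The other 2 were at 0.0428 to 122 and 13.1 to 55.7. Of the 4, ENSMUST00000119978.1 and ENSMUST00000210815.1 were past the threshold neither by limma-voom nor without GF replicates 2 or 5 or SPF replicate 4, with edgeR adjusted p of 0.0646, 0.0524 and 0.0538 for the first and 0.116, 0.103 and 0.0617 for the second, which also had 0.0869 without GF replicate 1. With the short-transcript share as a covariate only ENSMUST00000129314.1 stayed past it, and the fitted log2 fold changes of ENSMUST00000060766.15, ENSMUST00000119978.1 and ENSMUST00000210815.1 went from 14.5, 14.2 and -13.8 to 7.27, 3.43 and -5.47.

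Of the 6195 transcripts in the pull-down enriched class of ileum, 387 were higher and 505 lower in GF mice. Of the 5605 tested in the depleted class, 215 were higher and 83 lower. Called transcripts differed in length by direction: those higher in GF ileum had a median of 3146 bases and those lower a median of 1089 bases, where all tested transcripts had 1976. Transcripts of up to 1000 bases held 18.6% ± 2.11 of counts in SPF Cre-positive ileum (SD, n = 5) and 10.9% ± 1.01 in GF (SD, n = 3). This difference had an exact two-sided permutation p of 0.0179, the smallest these sizes allow, and 0.0714 after Benjamini-Hochberg adjustment over 9 comparisons. The count of 4315 was 6139 without the sparse libraries and 6 with the short-transcript share as a covariate, and 2817 with no expression filter, 11613 by DESeq2 and 14371 by limma-voom. Leaving out single libraries gave 1292, 417 and 889 (GF replicates 1, 2 and 5) and 2438 and 926 (SPF replicates 2 and 4).

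**Figure D3:**
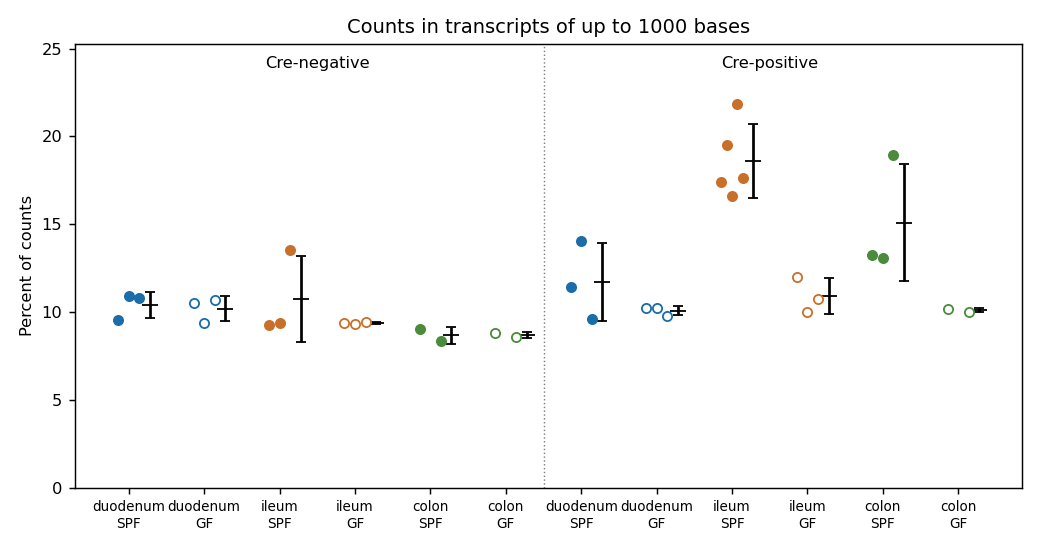
Percent of estimated counts per library in transcripts of up to 1000 bases (vertical axis), by group, 1 point per library, filled for SPF and open for GF. Black bars give the mean and SD. SPF Cre-positive ileum is at 18.6% ± 2.11 (n = 5) and GF Cre-positive ileum at 10.9% ± 1.01 (n = 3).

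In colon 14 transcripts differed between GF and SPF Cre-positive libraries, 8 higher and 6 lower in GF mice. ENSMUST00000108980.8 was at 19.3 CPM ± 7.66 and ENSMUST00000108964.1 at 8.89 CPM ± 3.89 in GF colon (SD, n = 2), both with 0 counts in the 3 SPF libraries. They were at least 158-fold and at least 72.6-fold higher (edgeR adjusted p of 0.044 and 0.0417). ENSMUST00000171601.7 and ENSMUST00000174847.7 were at 2.82 CPM ± 1.83 and 1.45 CPM ± 1.00 in SPF colon (SD, n = 3) and had 0 counts in the 2 GF libraries, at least 24.7-fold and at least 12.8-fold lower (edgeR adjusted p of 0.0258 and 0.0417). The background shared the first 2 differences. ENSMUST00000108980.8 and ENSMUST00000108964.1 were at 14.9 CPM ± 4.41 and 8.52 CPM ± 3.73 in GF Cre-negative colon (SD, n = 2). In SPF Cre-negative colon (n = 2) they were at 0.0268 CPM ± 0.0379 (SD) and 0 counts. The other 2 were at 0.772 CPM ± 0.0765 and 0.442 CPM ± 0.154 in GF Cre-negative colon (SD, n = 2). In SPF Cre-negative colon these were at 1.3 CPM ± 0.131 and 0.317 CPM ± 0.182 (SD, n = 2). None of the 4 was past the threshold without GF replicate 1 or without GF replicate 2, with edgeR adjusted p of 0.0643 to 0.267. ENSMUST00000108980.8 was not past it without SPF replicates 1, 2 or 3 either (0.0891, 0.0649 and 0.0514), nor ENSMUST00000108964.1 without SPF replicate 1 (0.055). None of the 4 was past it with the short-transcript share as a covariate or in a fit of the compared groups alone, and ENSMUST00000174847.7 was not past it with no expression filter or without the sparse libraries. The count was 48 without the sparse libraries, 3 with the short-transcript share as a covariate, 32 with library size as the only scaling, 29 with RLE size factors, 9 with no expression filter, 0 in a fit of the compared groups alone, 4316 by DESeq2 and 3962 by limma-voom. It was 9 without GF replicate 1, 5 without GF replicate 2, 31 without SPF replicate 2 and 25 without SPF replicate 3.

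In duodenum no transcript passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 1359 transcripts, where 2837 would be expected by chance. This does not show that GF and SPF duodenum were alike. In the simulation 4-fold changes were recovered at 4.48% and 16-fold changes at 42.4% in duodenum. Of 44 tested transcripts selected below because they separate every GF from every SPF library, 0 were called here. Their median log2 fold changes in duodenum were 6.63 for those higher in GF and -6.91 for those higher in SPF. DESeq2 called 319 and limma-voom 34, and edgeR called 12 without the sparse libraries, 3 with no expression filter and 1 with the short-transcript share as a covariate. Of the transcripts called in ileum, 87.2% had the same sign of GF minus SPF in duodenum and 88.3% in colon, which come from separate libraries. Their medians were 0.29 (higher in GF ileum) and -0.40 (lower) on the log2 scale in duodenum, and 0.66 and -1.18 in colon. The same transcripts, signed to the SPF direction, differed as much or more between libraries of 1 group, with median deviations from the other libraries of 0.723 and -0.658 in duodenum SPF Cre-positive replicates 5 and 6, and of 1.23 and -0.817 in colon SPF Cre-positive replicates 3 and 2. The share of equal signs was not recomputed without these libraries, nor computed over all tested transcripts. Over all 56732 transcripts GF minus SPF had a Spearman correlation of 0.345 between ileum and duodenum and 0.371 between ileum and colon. The labels do not state whether libraries of different regions come from different mice.

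**Figure D4:**
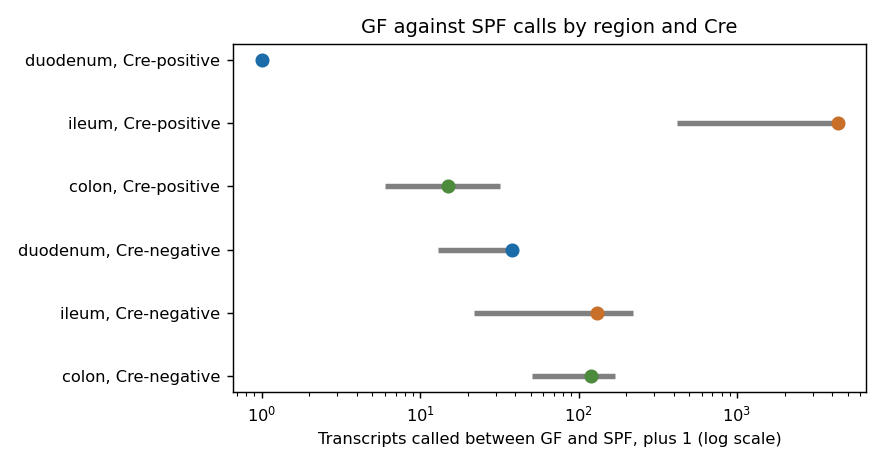
Transcripts called between GF and SPF mice, plus 1, on a log axis, by region and Cre status. Points give the count from all libraries and grey bars the range when each compared library is left out in turn, 417 to 4302 for Cre-positive ileum.

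RNA recovered without the tag was compared in the same way. In Cre-negative libraries 37 transcripts differed between GF and SPF mice in duodenum (30 higher and 7 lower in GF), 129 in ileum (34 and 95) and 119 in colon (40 and 79), of 59962 tested. ENSMUST00000188914.6 was at 12.5 CPM ± 2.7 in GF Cre-negative ileum (SD, n = 3) and 9.68 CPM ± 0.337 in GF Cre-negative colon (SD, n = 2), with 0 counts in the SPF libraries, at least 122-fold and at least 118-fold higher (edgeR adjusted p of 0.0133 and 0.0277). It was not past the threshold in ileum without GF replicate 3 (edgeR adjusted p of 0.0603), nor in colon without any 1 of the 4 libraries (0.0681 and 0.0861 without GF replicates 1 and 2, 0.155 and 0.0883 without SPF replicates 1 and 2), nor in colon by limma-voom, nor in either region in a fit of the compared groups alone. ENSMUST00000103418.2 was at 37.4 CPM ± 17.2 in SPF Cre-negative duodenum (SD, n = 3) and had 0 counts in GF, at least 396-fold lower in GF mice (edgeR adjusted p of 0.00763). In ileum it was at 315 CPM ± 271 in SPF (SD, n = 3) and had 2 counts over the GF libraries, a ratio of 15000 with a counting interval of 4160 to 124000 (edgeR adjusted p of 0.00288). This transcript was not past the threshold in either region in a fit of the compared groups alone, nor in duodenum by limma-voom. Transcripts of the class depleted by the pull-down made up 31 of those lower in GF ileum and 48 of those lower in GF colon. In ileum 66 transcripts were called in the same direction with and without Cre, where independent lists would share 4.5, and in colon 6, where they would share 0.015. GF minus SPF had a Spearman correlation of 0.563 across 53162 transcripts between Cre-positive and Cre-negative ileum, 0.112 in duodenum and 0.117 in colon. The SPF Cre-negative ileum group holds a sparse library, replicate 4, in which the transcripts called in Cre-positive ileum deviated toward the SPF side by a median of 1.34, against -0.585 and -0.658 in replicates 2 and 3, and the correlation without that library was not computed.

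Fits of the compared groups alone called 1, 1 and 0 transcripts in Cre-negative duodenum, ileum and colon, DESeq2 called 331, 2796 and 1132, limma-voom called 20, 1150 and 34, and without the sparse library edgeR called 195 in ileum and 193 in colon. Leaving out 1 Cre-negative library gave 18, 22, 16 and 12 in duodenum (GF replicates 2 and 3, SPF replicates 1 and 4), 77, 38, 21, 60, 219 and 195 in ileum (GF replicates 1, 2 and 3, SPF replicates 2, 3 and 4), and 50 and 52 in colon (GF replicate 2, SPF replicate 1).

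Whether the GF-to-SPF ratio differed between tagged ribosomes and the background was tested as an interaction of Cre with microbiota. A call can come from a change in the background as well as from one on tagged ribosomes. It does not show that the change on tagged ribosomes was the larger. It was past the threshold for 6 transcripts in ileum (5 with a higher GF-to-SPF ratio in Cre-positive libraries and 1 with a lower one) and for 9 in colon (3 and 6), of 64798 tested. In duodenum no transcript passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2076 had an unadjusted p under 0.05, DESeq2 called 403 and limma-voom 0. Without GF Cre-negative replicate 3, GF Cre-positive replicate 5, SPF Cre-negative replicate 1 or SPF Cre-negative replicate 6 edgeR called 3, 2, 2 or 1 in duodenum. The ileum count was 1903 without the sparse libraries and 699 without SPF Cre-negative replicate 4 alone. It was 0 without GF Cre-negative replicate 3, GF Cre-positive replicates 1 or 5, SPF Cre-negative replicate 2 or SPF Cre-positive replicate 4. Without GF Cre-negative replicates 1 or 2 it was 2 or 3, without GF Cre-positive replicate 2 it was 11, and without SPF Cre-negative replicate 3 or SPF Cre-positive replicates 2 or 3 it was 3, 2 or 12. DESeq2 called 1181 and limma-voom 2994 in ileum, and 1115 and 117 in colon. The colon count was 37 without the sparse libraries, 23 and 59 without GF Cre-negative replicate 1 or SPF Cre-negative replicate 2, 5 and 3 without GF Cre-positive replicates 1 or 2, and 22, 31 and 21 without SPF Cre-positive replicates 1, 2 or 3. Fits of the compared groups alone called 1 in ileum and 0 in colon, and with no expression filter edgeR called 0 in ileum.

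Regions were compared within SPF Cre-positive libraries. Ileum differed from duodenum in 1393 transcripts, 207 higher and 1186 lower in ileum. Colon differed from duodenum in 522 transcripts, 199 higher and 323 lower in colon, and from ileum in 1244, 796 higher and 448 lower in colon. ENSMUST00000162528.8 was lower in colon. It was at 20.5 CPM ± 6.58 in SPF duodenum (SD, n = 3) and 5.4 CPM ± 2.93 in SPF ileum (SD, n = 5), and had 0 counts in the 3 SPF colon libraries that both comparisons share, at least 168-fold and at least 44.1-fold lower (edgeR adjusted p of 8.5e-05 and 0.000237). Neither call was made in a fit of the compared groups alone. In GF Cre-positive libraries, which are separate, the same contrasts called 64, 133 and 115 transcripts. Of these, 49, 107 and 83 were also called in SPF mice in the same direction and 0 in the opposite one, where independent lists would share 0.7, 0.6 and 1.2. Over all transcripts the Spearman correlations between the SPF and GF contrasts were 0.178, 0.18 and 0.0221. Of the transcripts called in SPF mice, 77.7%, 93.5% and 76.4% had the same sign in GF mice. The median log2 fold changes of those called higher in SPF mice were 2.14, 2.08 and 1.52 in SPF and 1.08, 1.18 and 0.32 in GF mice, and of those called lower -2.22, -2.92 and -2.66 in SPF and -0.29, -1.63 and -0.97 in GF mice.

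Transcripts higher in SPF ileum than in SPF duodenum had a median length of 1581 bases and those lower a median of 3134, a contrast that moves with the share of short transcripts shown above. With that share as a covariate, the counts were 10 for ileum against duodenum, 347 for colon against duodenum and 1266 for colon against ileum. Without the sparse libraries they were 3027, 629 and 2788, in fits of the compared groups alone 205, 0 and 32, by DESeq2 7635, 3706 and 6154, and by limma-voom 5826, 1447 and 12369. With library size as the only scaling, which moved the median of colon against ileum by -0.30, the transcripts higher and lower in colon than in ileum numbered 480 and 672, so which direction holds more calls depends on the scaling. Leaving out 1 library gave 680, 2296, 166, 559, 524 and 401 for ileum against duodenum (duodenum replicates 4, 5 and 6, ileum replicates 1, 2 and 4). It gave 237, 283 and 326 for colon against duodenum (duodenum replicates 4 and 6, colon replicate 1). For colon against ileum it gave 547, 476, 5502, 611, 782, 566 and 3154 (colon replicates 1, 2 and 3, ileum replicates 1, 2, 4 and 5).

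Whether the GF to SPF difference itself depended on region was tested over the Cre-positive libraries. It did for 3 transcripts, each detected in all libraries of GF or of SPF ileum and at 0 or 1 count in total in the other. ENSMUST00000165223.7 had 0 counts in all 5 SPF ileum libraries and was at 18.9 CPM ± 3.59 in GF ileum (SD, n = 3), against 11.2 ± 2.63 in SPF and 16.1 ± 2.1 in GF duodenum (SD, n = 3 each) and 9.18 ± 5.43 in SPF (SD, n = 3) and 12 ± 6.88 in GF colon (SD, n = 2). ENSMUST00000129314.1 was at 53.5 CPM ± 13.7 in SPF ileum (SD, n = 5) with 0 counts in GF ileum, against 35.1 ± 21.3 and 17.6 ± 5.65 in SPF and GF duodenum (SD, n = 3 each) and 50.5 ± 35 (SD, n = 3) and 35.1 ± 4.36 (SD, n = 2) in SPF and GF colon. ENSMUST00000153290.7 was at 4.09 CPM ± 1.55 in SPF ileum (SD, n = 5) and had 1 count over the 3 GF ileum libraries, against 10.2 ± 1.73 and 11.2 ± 2.27 in SPF and GF duodenum (SD, n = 3 each) and 3.79 ± 1.48 (SD, n = 3) and 6.72 ± 1.1 (SD, n = 2) in SPF and GF colon. The background shared part of this: ENSMUST00000129314.1 and ENSMUST00000153290.7 had 0 counts in all 3 GF Cre-negative ileum libraries too, against 29.5 CPM ± 29.4 and 6.48 CPM ± 8.6 in SPF Cre-negative ileum (SD, n = 3 each), where ENSMUST00000153290.7 was at 0 in replicate 3 and highest, at 16.2 CPM, in the sparse replicate 4. ENSMUST00000165223.7 was at 14.6 and 15.1 CPM in SPF Cre-negative ileum replicates 2 and 3 and at 0 in the sparse replicate 4, so its 0 counts in SPF Cre-positive ileum were not shared by the other 2 background libraries. Adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 0.000754, 0.00249 and 0.00593. So the 4315, 14 and 0 calls of ileum, colon and duodenum do not by themselves show that regions differ, and 3 transcripts passed the test of that difference. That number was 62 without the sparse libraries, 121 without colon SPF replicate 3 alone, 786 by DESeq2 and 1261 by limma-voom. It was 7 without ileum GF replicate 5, 6 without colon SPF replicate 2, and 5 without colon GF replicate 2, duodenum SPF replicates 5 or 6, or ileum SPF replicate 2. Without ileum GF replicate 1 it was 2, and ENSMUST00000153290.7 had an edgeR adjusted p of 0.0534.

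**Figure D5:**
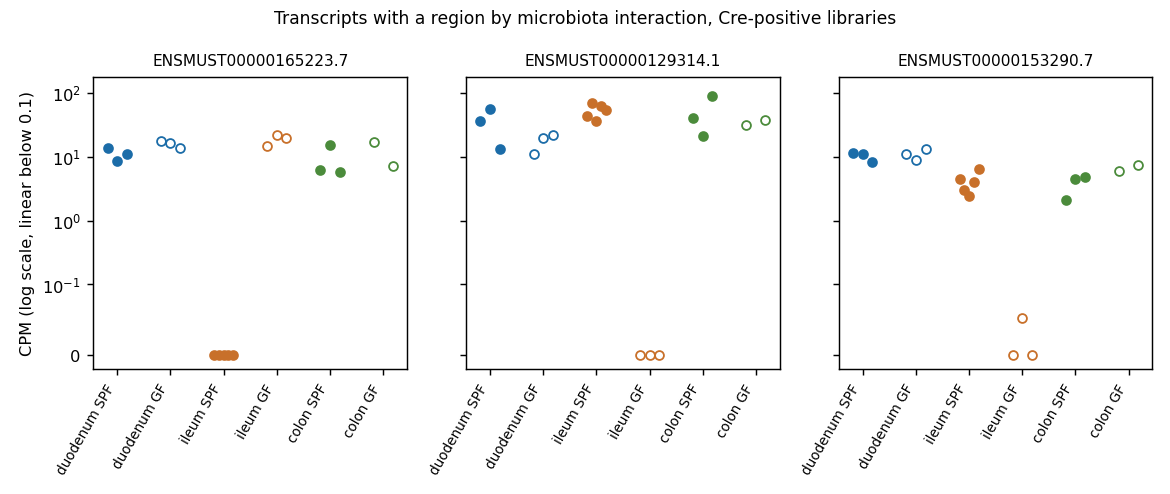
CPM (vertical axis, log scale above 0.1 and linear below) of the 3 transcripts whose GF to SPF difference depended on region, by region and microbiota in Cre-positive libraries, 1 point per library, filled for SPF and open for GF. ENSMUST00000165223.7 is at 0 in all 5 SPF ileum libraries and ENSMUST00000129314.1 at 0 in all 3 GF ileum libraries.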

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

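The tests of the composition of the sparse libraries, of Cre-positive material, of depth by thinning, of the covariate and of the fits without those libraries were chosen only after the data were seen, while the splits of the samples were planned.

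The tests of a difference between differences found 6 transcripts in ileum and 9 in colon whose GF to SPF difference depended on Cre, and 3 whose difference depended on region among Cre-positive libraries. These are listed because the difference itself was tested. For ileum, 7 of 100 splits of the samples that exchanged GF and SPF libraries within Cre status called as many transcripts as the real 6, so chance was not excluded. The highest of the other splits called 8113, and it put SPF Cre-positive replicates 1, 2 and 4 together, which points to a structure of the samples. In duodenum the real count was 0, all 100 splits called as many, and the highest of the others called 2. The colon groups have 2 libraries each in 3 of 4 cases. Their interaction was not split, although the colon pull-down was, so chance was not weighed for the 9 transcripts in colon.

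For the pull-down, 1 split of 100 in duodenum, 1 of 100 in ileum and 1 of 60 in colon, the real one in each case, called as many transcripts in either direction as the real 22591, 20619 and 20295. The highest of the other splits called 11649, 5607 and 16441. This excludes chance as the source of these counts as far as libraries vary independently, which the labels do not state. For GF against SPF in duodenum the 10 splits are too few for a share under 0.05. The real counts were 0 in Cre-positive libraries, where all 10 splits called as many and the highest other called 3, and 37 in Cre-negative libraries, where 1 did and the highest other called 3. In Cre-negative ileum the 10 splits are too few as well, with a real count of 129 in 1 split and a highest other of 2. Colon against duodenum also has 10 splits, too few, with a real count of 522 in 1 split and a highest other of 79. For ileum against duodenum 1 of 56 splits called as many as the real 1393, but the highest other called 1337 and set SPF ileum replicates 1, 2 and 4 apart. For colon against ileum 4 of 56 splits called as many as the real 1244, so chance was not excluded, and the highest other, at 11141, parted the 3 sparse Cre-positive SPF libraries of the 2 regions from the rest, a structure of the samples.

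The first pattern weighed is the 4315 transcripts called between GF and SPF Cre-positive ileum. Of 56 splits 1, the real one, called as many, the smallest share these sizes allow, and the highest other called 491. This excludes chance for this count only as far as libraries vary independently, and the labels do not state that each came from its own mouse. The share was not adjusted for the number of comparisons split. At an unadjusted p under 0.05 by edgeR's quasi-likelihood test the splits lay closer, with 16237 transcripts in the real split and 15049 in the highest other. Depth was excluded, since libraries thinned to one depth gave 5272. A composition shared with the sparse libraries stays open: the same transcripts, signed to the SPF direction, deviated by a median of 1.23 on the log2 scale in colon SPF Cre-positive replicate 3 from the other 2 libraries of its group, which all come from SPF colon. Part of the ileum calls may therefore follow how these libraries were made or recovered, and duodenum SPF Cre-positive replicate 5 deviated by 0.723. The 6139 calls without the sparse libraries cannot decide this, since the composition still differed. SPF Cre-positive ileum replicates 1, 3 and 5, which stayed, had short-transcript shares of 17.4%, 16.62% and 17.63%. GF Cre-positive ileum replicates 1, 2 and 5 had 11.99%, 9.993% and 10.76%. Their shares of missing transcripts were 6.771%, 4.731% and 5.178% in SPF and 2.744%, 3.218% and 2.38% in GF. The microbiota, which the design names, stays open as well, as does a difference in diet, which was not tested, and the short-transcript share does not overlap between GF and SPF Cre-positive ileum, so the covariate, with which 6 transcripts are called, removes much of the group difference along with it.

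The second pattern is ileum SPF Cre-negative replicate 4, which lay apart from the other Cre-negative libraries on the second principal component, at 311. A swap with a Cre-positive library was excluded, since pull-down enriched transcripts held 16.71% of its counts. The other Cre-negative libraries held 13.26% to 20.1%, and Cre-positive libraries 45.55% or more. Some Cre-positive material was not excluded, since the other 2 SPF Cre-negative ileum libraries held 13.26% and 13.36%. On the first principal component this library lay at -53.3, nearer the Cre-positive libraries than any other Cre-negative library. Its highest Spearman correlation, 0.8229, was with ileum SPF Cre-positive replicate 4. The transcripts called in Cre-positive ileum deviated in this Cre-negative library by a median of 1.34 toward the SPF side. It may therefore share the composition of the sparse libraries, and no biological explanation was tested for a single library.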

How the results depend on the processing

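The alternatives without the sparse libraries, with the short-transcript share as a covariate and with libraries thinned to one depth were chosen after the data were seen, and the others before. Of 424 values of named transcripts under alternatives, 424 kept their direction, 362 also kept their side of the threshold, 62 lost it and 0 reversed. These transcripts were selected in the same libraries for large changes without overlap, or for the smallest p, so a kept direction says little. Of 283 counts under alternatives, 146 were within 1.5 times the reported count. Where a count moved further, the cause was not tested unless a sentence gives it.

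Pull-down enriched transcripts in duodenum, ileum and colon numbered 6032, 5601 and 5245 with library size as the only scaling, and 6187, 4923 and 3754 in GF libraries alone and 6207 in SPF duodenum alone, where fewer libraries were used. Leaving out 1 library gave 8439 to 9095, 7849 to 9176 and 6529 to 8850. In ileum the transcripts higher and lower in the pull-down numbered 10964 and 15461 by DESeq2, with a median shift of -0.14, and RLE size factors shifted that median by -0.15.

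For GF against SPF in Cre-positive duodenum, ileum and colon, DESeq2 called 319, 11613 and 4316, limma-voom 34, 14371 and 3962, and edgeR with no expression filter 3, 2817 and 9. With the short-transcript share as a covariate the counts were 1, 6 and 3. In ileum that covariate took the fitted log2 fold change of ENSMUST00000060766.15 from 14.5 to 7.27 (adjusted p of 0.604, with 2.7e-17 to 0.6 over all its alternatives) and of ENSMUST00000119978.1 from 14.2 to 3.43 (0.83, with 3.1e-42 to 0.83 over all). It took ENSMUST00000210815.1 from -13.8 to -5.47 (0.692, with 8.2e-10 to 0.69 over all) and ENSMUST00000129314.1 from -13.3 to -11.4 (0.00162, with 2.8e-19 to 0.11 over all). In colon RLE size factors gave 29, library size alone 32, and a fit of the compared groups alone 0, where fewer libraries set the spread. Without the sparse libraries duodenum had 12 and colon 48. DESeq2 called 1532 higher and 2784 lower in GF colon, and library size alone shifted the colon median by 0.22. Leaving out 1 library gave 0 to 0, 417 to 4302 and 5 to 31.

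In Cre-negative duodenum, ileum and colon, DESeq2 called 331, 2796 and 1132, limma-voom 20, 1150 and 34, and fits of the compared groups alone 1, 1 and 0. Without the sparse libraries ileum had 195 and colon 193. DESeq2 called 170 higher and 161 lower in duodenum and 1120 higher and 1676 lower in ileum, and library size alone shifted the colon median by 0.11. Leaving out 1 library gave 12 to 35, 21 to 219 and 50 to 170.

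The interaction of Cre with microbiota had 403, 1181 and 1115 calls by DESeq2 in duodenum, ileum and colon. limma-voom called 2994 in ileum and 117 in colon, a fit of the compared groups alone 1 and 0, and edgeR with no expression filter 0 in ileum. Without the sparse libraries ileum had 1903 and colon 37. Of the DESeq2 calls 744 were higher and 437 lower in ileum and 497 higher and 618 lower in colon. RLE size factors called 5 higher and 2 lower in ileum. The median shifts were 0.13 by DESeq2, 0.16 with library size alone and 0.12 with RLE size factors in ileum, and 0.12 with library size alone in colon. Leaving out 1 library gave 0 to 3, 0 to 699 and 3 to 59.

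For ileum against duodenum, colon against duodenum and colon against ileum, DESeq2 called 7635, 3706 and 6154, limma-voom 5826, 1447 and 12369, and fits of the compared groups alone 205, 0 and 32. With the short-transcript share as a covariate the first 2 had 10 and 347. Without the sparse libraries the first had 3027 and the last 2788. For colon against ileum, where 796 were higher and 448 lower in colon, library size alone gave 480 and 672 and DESeq2 3056 and 3098, so that the direction with more calls changed. For ileum against duodenum more were lower than higher under every scaling, with 540 higher and 1304 lower by library size alone and 2766 and 4869 by DESeq2. Library size alone shifted the medians of the 3 contrasts by 0.11, -0.21 and -0.30. Leaving out 1 library gave 166 to 2296, 237 to 690 and 476 to 5502. The interaction of region with microbiota had 786 calls by DESeq2, 1261 by limma-voom and 62 without the sparse libraries, and 2 to 121 when 1 library was left out.

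Replicate numbers do not pair libraries by the rule fixed beforehand: in each pair of groups that share 3 numbers, at least 1 correlation between libraries with the same number, after group means were removed, was not above 0.1. These correlations were 0.0178 to 0.123 between SPF and GF Cre-positive ileum, 0.0763 to 0.0847 between GF Cre-negative duodenum and ileum, -0.123 to 0.285 between SPF Cre-negative and Cre-positive ileum, and -0.471 to 0.176 between SPF Cre-positive ileum and colon. As a hint from the data, of these 4 pairs of groups 1, GF Cre-negative duodenum and ileum, had every library correlating best with its own number. With a block for the replicate number, GF against SPF gave 0 in Cre-positive ileum and colon, 38 in Cre-negative ileum and 69 in Cre-negative colon, and the 4 named ileum transcripts had adjusted p of 0.111 to 0.163 at fitted changes close to those reported. The interaction with Cre gave 135 in ileum and 15 in colon. Ileum against duodenum, colon against ileum and the interaction of region with microbiota gave 0.

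Where leaving out a library leaves 1 in its group, that library is assumed to vary like the others. Depth limits what a count of 0 can show to 3 counts per library. Offsets for transcript length, sums per gene, tests of gene lists and Snap25 and Cartpt by name were not run.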

Other observations

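The tests below were not planned before the data were examined, although what each would show was written before its own result was seen, and the transcripts named were chosen after their values were seen.

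Across regions and Cre status, 45 of 64798 transcripts had every one of the 16 GF libraries on one side of every one of the 19 SPF libraries, 37 higher in GF and 8 higher in SPF mice. These 45 held 43 different count profiles. If all labellings of the libraries, without regard to region and Cre status, were equally likely, 3.2e-05 would be expected. Of 100 exchanges of GF and SPF labels within region and Cre status, 1, the real one, separated as many, and the highest of the others separated 0. This excludes chance as far as libraries vary independently, and the labels do not state that each came from its own mouse. The transcript with the widest gap, ENSMUST00000108964.1, was at 8.99 CPM ± 3.56 in GF libraries (SD, n = 16) and had 0 counts in all 19 SPF libraries. ENSMUST00000103410.2 was at 65.7 CPM ± 88.5 in SPF libraries (SD, n = 19) and at 0.288 ± 0.236 in GF libraries (SD, n = 16). Of the transcripts tested, 43 of 44 were called in Cre-positive ileum, 5 in Cre-positive colon and 0 in Cre-positive duodenum by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 25, 31 and 25 of 45 in Cre-negative duodenum, ileum and colon. Since these transcripts were selected for a separation in all regions, neither the counts of calls nor the sizes of their changes compare the regions. None of the 45 was enriched by the pull-down in all 3 regions, and 3 were depleted in all 3. Among all 64798 transcripts 5600 were enriched and 3863 depleted in all 3, and a difference in these shares was not tested.

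A candidate explanation is a genetic difference between the GF and SPF mice, which would act in every region with and without Cre, and the other is the microbiota. Only 2 of the 45 had 0 counts in all libraries of one status, under the 10% set beforehand as arguing against a genetic difference. That limit was too strict, since kallisto divides shared reads and 29 of the 45 (64.4%) averaged under 3 counts per library on the lower side. All GF libraries come from GF mice and all SPF libraries from SPF mice, so a genetic difference and the microbiota cannot be told apart here. The same holds for a difference in diet, a word carried by the names of all SPF tables and no GF table and not explained by the labels, which was not tested.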
